A study of Mus musculus with 9 samples.

How the data were processed

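RNA sequencing measured transcript levels in germ cells from the testes of adult mice. The series holds 9 libraries, 3 from spermatogonia of types A and B, 3 from pachytene spermatocytes and 3 from round spermatids, and calls the 3 of each stage biological replicates. The labels do not say whether they came from separate animals or how the cells were isolated. A p-value here therefore measures the spread between these samples, except those for long non-coding RNAs paired with coding genes. These were taken over pairs of features, not over libraries. Per the labels' protocols, RNA was extracted with a Qiagen kit, 1 µg of total RNA went into each stranded Illumina TruSeq library, and reads were paired and 100 bp long.

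The submitters' processing notes name FastQC, Trim Galore, TopHat2 2.0.12, Cuffdiff 2.2.1 and the mm10 build of the mouse genome. The order of these steps, their options, the annotation release and whether counting used the strand are not given in the sources used here. The authors deposited FPKM values, fragments per kilobase of transcript per M fragments, per feature and library in a pair of tables. The first, called the mRNA table here, lists 39336 features of every gene type, 20660 of them protein-coding, and the second, called the lncRNA table, lists 5385 features. The tables were scaled separately, so tests stay within a table, and 4495 identifiers occur in both. The authors also deposited a table per stage transition of the features they called, with stage FPKM, a log2 fold change, and a p-value and q-value per feature. The largest deposited q-value is 0.0500, and the deposited log2 column for lncRNAs in pachytene against spermatogonia was not used because it holds spreadsheet errors. No per-sample column was left without a sample.

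Depth is not stated. The low FPKM values of single-transcript genes of at least 2000 nt fall on steps, and the smallest step implies 28.1, 48.4 and 56.4 M fragments (M, mega) for spermatogonia replicates 1 to 3, 25.6, 20.8 and 26.0 M for pachytene, and 21.6, 25.7 and 17.4 M for round spermatids. The same estimate gives 0.344 to 0.98 M for the libraries of the lncRNA table, which is thus scaled to a smaller total. Over 254 features, its values were by median 24.8 to 48.4 times those of the mRNA table. A single fragment is therefore a larger step in FPKM there, and this does not imply fewer fragments per feature. A fixed FPKM filter or pseudocount is laxer in that table, and folds from or to 0 are larger. The fragment numbers are estimates from the values, and no interval was made from them.

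Feature identifiers were matched to GENCODE M21, which is on GRCm38, the assembly that mm10 names. In the mRNA table, 38505 identifiers matched and 38440 of them overlapped their M21 position; in the lncRNA table, 5189 matched and 5188 overlapped, 59 of them protein-coding in M21. The release the authors used is not known, so gene types and exon overlaps are those of M21. Coordinates are 1-based, on GRCm38. In the mRNA table, 31 features with a blank library were left out.

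Before the data were examined, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed. Values were taken as log2(FPKM + 0.1), for features with at least 0.5 FPKM in at least 3 libraries, which left 17987 features of the mRNA table and 4009 of the lncRNA table. One limma 3.58.1 model per table (R 4.3.3), with a mean trend and all 9 libraries, gave log2 fold changes, standard errors and moderated p-values, adjusted by Benjamini-Hochberg. A feature counts as changed at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. A fold change on this scale understates the change of low features, and features listed at 0 in every library of a stage are given no fold. Every ± is an SD over 3 libraries unless SE is written.

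The 19 fixed lists cover germ cell stages and functions, DNA replication, glycolysis, cytosolic ribosomal proteins, 7 other cell types of the testis and known lncRNAs. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 19 lists of a transition, and again with the correlation estimated from the data. X-linked features were set against autosomal ones by the difference of their median log2 fold changes, with camera, and by an exact two-sided permutation test of the per-library difference, which cannot go below 0.1 with 3 libraries against 3. A feature counts as highest in a stage when limma calls it above both others. The named-gene rule takes, per transition, the 5 called features with the largest rise and fall in the mRNA table (at least 10 FPKM in the higher stage), the 6 in the lncRNA table (at least 1 FPKM), up to 4 called members per list with the largest change, and every called known lncRNA. Other members named as exceptions to a count, the genes of the Y chromosome and the X-linked genes with autosomal copies were chosen after their values were seen.

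The fit was tested on simulated data with 200 changed features per fold size. At 4-fold it recovered 89.5% (pachytene against spermatogonia) and 90% (round spermatids against pachytene) of 200 among 17987 mRNA-table features, and 20% and 32.5% among 4009 lncRNA-table features. At 2-fold the recovered shares were 32.5% and 40% in the mRNA table and 1% and 0% in the lncRNA table. In the real data many more features were called, 12154 of 17987 and 2267 of 4009 in pachytene against spermatogonia. The adjustment depends on the share of changed features, so the simulated shares do not measure what the real calls miss.

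That first set held a pseudocount of 1 FPKM, no filter, library medians made equal, the replicate number as a block, only the 6 libraries compared, no fold threshold, an estimated correlation and each library left out in turn. Added after the data were seen were replicates 1 and 2 only, protein-coding features only, lncRNAs taken from the mRNA table, lncRNAs that share no exon with a coding gene, and a round spermatid share subtracted from the pachytene libraries. That share is the ratio to the round spermatid mean under which 1% of the 2488 coding features with at least 50 FPKM in round spermatids lie, 7.34%, 7.44% and 7.32% for the pachytene libraries. Also added was a rescaling that divides each library of the lncRNA table by its median ratio to the mRNA table over 254 features. The authors' calls cover only called features and were set beside the counts, not refitted. Reads, isoforms and splicing were not analysed here. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.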

Results

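Transcripts of spermatogonia, pachytene spermatocytes and round spermatids were measured by stranded RNA sequencing, in 3 libraries of each stage. Spermatogonia are the mitotic germ cells, pachytene spermatocytes are in meiotic prophase, and round spermatids are the haploid cells that form sperm. The series asks, by its title, which long non-coding RNAs are expressed as these cells develop, and it lists coding genes beside them. The lncRNA table is on a larger FPKM scale, by median 24.8 to 48.4 times that of the mRNA table over 254 features. The same pseudocount and filter are thus laxer in it, and its folds from or to 0 are larger. Within a stage, log2 values of library pairs correlated across features at 0.969 to 0.986 in the mRNA table and 0.845 to 0.898 in the lncRNA table, and between stages at 0.375 to 0.864 and 0.121 to 0.779 (features are not independent replicates). In round spermatid replicate 2, the microRNA feature Mir1938 is listed at 743497 FPKM and at 0 in the other libraries, and it was not tested.

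The passage from spermatogonia to pachytene asks which genes change as germ cells enter meiosis. Genes of sperm structure and function were near 0 in the spermatogonia libraries and high in the pachytene libraries. Crisp2, a secretory protein of the acrosome and sperm tail, went from 0.0459 ± 0.0483 to 1528 ± 41.9 FPKM (n = 3 each; log2 fold change 13.41, SE 0.198, adjusted p = 1.24e-11). Ldhc, the testis form of lactate dehydrogenase, went from 0.353 ± 0.117 to 4240 ± 161 FPKM (log2 fold change 13.22). The lincRNA RP24-176G22.2 rose by 13.14, Spata4 by 13.02 and Cmtm2a by 12.91 on the log2 scale. The largest falls among features above 10 FPKM were small RNA genes listed at 0 in all 3 pachytene libraries. The snoRNA Gm22303 was listed at 37.1, 26.5 and 33.4 FPKM in the spermatogonia libraries, the snoRNA Gm23077 at 64.2, 12.04 and 27.9, and the snoRNA Gm22362 at 25.9, 76.7 and 98.1. The microRNA Mir1983 was listed there at 30.5, 48.8 and 31.6 FPKM, and the snoRNA Gm24451 at 25.02, 24.2 and 20.05.

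Markers of spermatogonia fell. Of 25 measured genes of undifferentiated spermatogonia, 16 fell, 2 rose and 7 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.000199; adjusted p = 0.178 with an estimated correlation). Zbtb16, a transcription factor of spermatogonial stem cells, fell from 11.7 ± 0.916 to 1.08 ± 0.0561 FPKM, Ret, the receptor subunit for GDNF, from 4.29 ± 0.421 to 0.337 ± 0.0230, and Dusp6 from 61.9 ± 4.60 to 4.42 ± 0.154. The exceptions were Id4 and Egr4, with Id4 at 3.70 ± 0.598 FPKM in spermatogonia and 75.2 ± 2.33 in pachytene. Of 16 genes of differentiating spermatogonia, 14 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.000191; adjusted p = 0.178 with an estimated correlation). Ccnd2, cyclin D2, fell from 22.1 ± 1.91 to 1.16 ± 0.166 FPKM and Crabp1 from 50.2 ± 7.65 to 2.56 ± 0.521, and X-linked Rhox13 fell by 3.73 on the log2 scale, while Dmrtb1 rose by 4.61 and Uhrf1 by 1.04. Of 33 DNA replication genes, 16 fell, 7 rose and 10 were not called, also adjusted over the list alone (adjusted p = 0.0215; adjusted p = 0.701 with an estimated correlation). The helicase subunit Mcm2 fell from 38.1 ± 4.85 to 2.49 ± 0.318 FPKM, Mcm4 from 23.8 ± 2.08 to 1.85 ± 0.254, and the licensing factor Cdt1 and thymidylate synthase Tyms fell (log2 fold changes -3.45 and -2.92).

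Genes of meiosis and of later germ cells rose. Of 26 genes of pachytene and the meiotic divisions, 22 rose, and 2, Ccnb3 and Cpeb1, fell, with the same counts adjusted over the list alone (adjusted p = 5.52e-05; adjusted p = 0.413 with an estimated correlation). Adam2, a sperm surface protein, rose from 0.0101 ± 0.00414 to 419 ± 4.25 FPKM, Pgk2, the testis phosphoglycerate kinase, from 0.0123 ± 0.0118 to 175 ± 3.46, and Spag6, an axonemal protein, from 0.483 ± 0.123 to 349 ± 2.75. Of 34 genes of the synaptonemal complex and recombination, 20 rose and 8 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.144), though it did with no filter (adjusted p = 0.0229). The cyclin-like Cntd1 rose by 5.99, Spo11, which makes meiotic DNA breaks, by 5.77, and Psmc3ip by 4.14 on the log2 scale, whereas X-linked Tex11 fell from 35.7 ± 3.34 to 2.01 ± 0.303 FPKM. Of 23 genes on the piRNA list, 19 rose and 2, Piwil4 and Fkbp6, fell, the same adjusted over the list alone (adjusted p = 0.000382; adjusted p = 0.466 with an estimated correlation). Piwil1, the pachytene piRNA-binding protein, rose from 0.903 ± 0.106 to 259 ± 7.19 FPKM, Tdrd6 from 0.0948 ± 0.0386 to 439 ± 11.9, and Mael from 71.3 ± 10.5 to 1195 ± 28.0. Rpl10l, which that list also holds, encodes a ribosomal protein and rose by 4.09 on the log2 scale.

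All 32 tested acrosome and sperm-egg binding genes and all 36 flagellum genes rose, the same adjusted over each list alone, and these calls hold with an estimated correlation. The acrosome list had a median log2 fold change of 6.91 (adjusted p = 1.89e-10; adjusted p = 0.0312 with an estimated correlation) and the flagellum list one of 6.99 (adjusted p = 2.26e-11; adjusted p = 0.0312 with an estimated correlation). Spata16 rose by 10.48, the outer dense fibre genes Odf4 and Odf1 by 10.47 and 9.44, and Tekt3 by 9.31 on the log2 scale, and Adam3 was listed at 0 in every spermatogonia library and at 421, 406 and 408 FPKM in pachytene. Of 20 genes of spermatid chromatin and transcription, 16 rose and 2, Taf7l and Brwd1, fell, also adjusted over the list alone (adjusted p = 0.000409; adjusted p = 0.178 with an estimated correlation). Prm1, a protamine, stood at 0.0240 ± 0.0416 FPKM in spermatogonia and 409 ± 48.2 in pachytene, Prm2 at 0.0132 ± 0.0229 and 343 ± 21.5, and the transition protein genes Tnp2 and Tnp1 rose by 10.78 and 10.01 on the log2 scale. Of 26 genes of glycolysis and its testis-specific copies, 15 rose and 10 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.494), with Gapdhs up by 8.47 and the glucose transporter Slc2a3 up from 3.95 ± 0.349 to 2037 ± 69.7 FPKM. Of 57 ribosomal protein genes 7 fell and none rose, the same adjusted over the list alone (adjusted p = 0.0215; adjusted p = 0.701 with an estimated correlation). Among them Rps4x, on the X, fell from 212 ± 13.4 to 6.63 ± 0.675 FPKM, X-linked Rpl10 from 252 ± 5.01 to 15.5 ± 0.741, and Rps16 and Rps19 fell (log2 fold changes -1.91 and -1.64). Spermatid genes at a small part of their round spermatid level in pachytene need not be expressed by pachytene cells, since a share of spermatid RNA in those libraries is not excluded. With a share of 7.32% to 7.44% of the round spermatid level subtracted the DNA replication and ribosomal lists no longer passed (adjusted p = 0.0555 and 0.0637). Their medians hardly moved, to -0.80 for DNA replication against -0.77 and to the same -0.22 for the ribosomal list, so the lost calls do not speak for such a share in these lists. Equal library medians also ended the call of the ribosomal list (adjusted p = 0.067).

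Markers of other testis cells were higher in spermatogonia than in pachytene, beside the spermatogonial genes that fell. Of 23 Sertoli markers 18 fell and 1, Rhox5, rose, the same adjusted over the list alone (adjusted p = 4.32e-06; adjusted p = 0.178 with an estimated correlation), with Amh at 35.4 ± 4.0 FPKM in spermatogonia and 0.842 ± 0.101 in pachytene, Aard at 461 ± 55.8 and 42.6 ± 1.80, Gstm6 at 120 ± 7.97 and 8.14 ± 0.510, and Krt18 at 1.95 ± 0.0674 and 0.0450 ± 0.0366. All 10 fibroblast and interstitial markers fell, also adjusted over the list alone (adjusted p = 0.000153; adjusted p = 0.300 with an estimated correlation). Col1a2, a collagen chain, stood at 56.6 ± 10.6 and 0.490 ± 0.0902 FPKM, and Col1a1, Col6a1 and Dcn fell (log2 fold changes -6.21, -5.84 and -5.64), with Dcn highest in spermatogonia replicate 3, at 126 FPKM against 23.0 and 20.1. Of 9 peritubular myoid markers 8 fell and 1, Actg2, rose, also over the list alone (adjusted p = 0.00844; adjusted p = 0.364 with an estimated correlation). Acta2, smooth muscle actin, was at 89.7 ± 10.1 and 6.49 ± 0.487 FPKM and Myh11 at 12.9 ± 1.82 and 1.23 ± 0.0559. The fold of Des (log2 fold change -3.09, adjusted p = 0.0371) is set by spermatogonia replicate 3, with 65.8 FPKM against 1.76 and 1.33 in the others. Des was still called without that library (log2 fold change -1.32, adjusted p = 0.000176), and its call ended in 9 alternatives that kept it. The rise of Actg2, from 2.76 ± 0.396 to 16.8 ± 0.300 FPKM, ended with the spermatid share subtracted (log2 fold change 0.02). Of 10 endothelial markers 8 fell, also over the list alone (adjusted p = 0.00445; adjusted p = 0.466 with an estimated correlation), with Kdr, Pecam1, Cdh5 and Egfl7 down (log2 fold changes -3.39, -3.25, -3.24 and -3.10).

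Blood cell lists did not pass the list test with all libraries. Of 13 macrophage markers 8 fell over all genes and 7 adjusted over the list alone, and 1, Mrc1, rose (adjusted p = 0.0842), with Tyrobp, Fcer1g, C1qc and Csf1r down (log2 fold changes -3.27, -2.51, -2.35 and -2.30). The fold of C1qc is set by spermatogonia replicate 3, at 7.29 FPKM against 0.701 and 0.705, and is -1.28 without it. The macrophage list passed without spermatogonia replicate 2 (median -2.43, adjusted p = 0.0345), and with a pseudocount of 1 FPKM the calls of C1qc and Csf1r ended. Of 5 erythroid markers 4 fell and 1, Alas2, rose, also over the list alone (adjusted p = 0.0925). The globin genes Hbb-bs and Hba-a1 stood at 100.0 ± 64.9 and 58.5 ± 22.5 FPKM in spermatogonia against 0.704 ± 0.357 and 0.314 ± 0.0659 in pachytene, Hbb-bt fell by 6.58, and Hba-a2 was listed at 0 in pachytene and at 1.97, 0.911 and 24.8 FPKM in spermatogonia. Spermatogonia replicate 3 stood apart in these lists: the mean log2 level of the erythroid list was 3.29, 3.09 and 5.12 in the 3 libraries, and that of the macrophage list -0.12, -0.29 and 2.15. Leydig markers went both ways, 4 up and 4 down of 11, also over the list alone (adjusted p = 0.710, median 0.07, mean -0.07, test direction down). Insl3, a Leydig cell hormone, rose from 3.45 ± 0.157 to 65.9 ± 3.79 FPKM and Hsd3b6 by 2.90 on the log2 scale, a call that ended with a pseudocount of 1 FPKM, while Hsd17b3 and Aldh1a1 fell (log2 fold changes -3.63 and -3.29).

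In all, 12154 of 17987 features of the mRNA table changed between spermatogonia and pachytene, 6584 up and 5570 down, and 14 of the 19 lists passed. With an estimated correlation 2 lists passed, those of the acrosome and the flagellum. The authors' deposited table lists 5756 features higher and 6015 lower in pachytene with no fold threshold, 4574 and 5023 of them at 2-fold. The balance turns in some alternatives, with 5775 up and 5910 down after the spermatid share was subtracted and 6949 up and 7002 down with no filter. Equal library medians moved the median change of all features from 0.26 to 0.36 on the log2 scale.

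**Figure D1:**
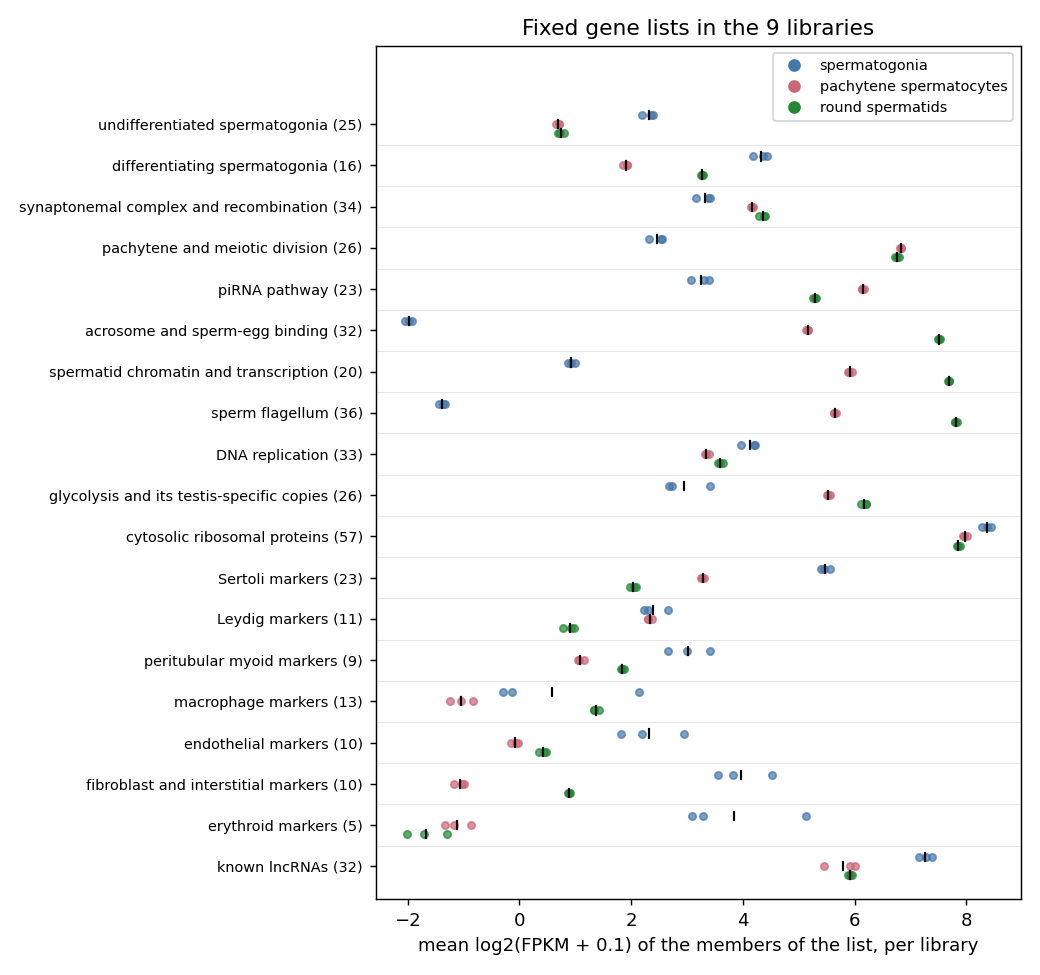
Mean log2(FPKM + 0.1) of the tested members of each fixed list, with a point per library, a black line at the mean of 3 libraries and the number of members in brackets. The acrosome and flagellum lists rise at each stage, and the spread between spermatogonia libraries is widest for the erythroid and macrophage lists.

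The step from pachytene spermatocytes to round spermatids asks which genes change after the meiotic divisions. Of the acrosome and flagellum genes 20 of 32 and 27 of 36 rose again, and 9 of 23 genes of the piRNA list fell, but none of these lists passed with an estimated correlation. Lyzl6, a sperm lysozyme-like protein, rose from 16.2 ± 0.407 to 225 ± 5.92 FPKM (n = 3 each; log2 fold change 3.79, SE 0.126, adjusted p = 1.27e-08), and Tnp1 from 340 ± 17.6 to 3860 ± 195 FPKM (log2 fold change 3.51). Hist1h1t, the testis linker histone, fell from 1973 ± 79.9 to 172 ± 5.61 FPKM and Piwil1 from 259 ± 7.19 to 33.0 ± 0.794. The largest changes by the fixed rule were mostly of small RNA genes, and all but Gm13821 are listed at 0 in at least 1 library of these stages, so single libraries set many of the folds. The snoRNA Gm23202 was listed at 0 in pachytene and at 11.2, 25.5 and 13.6 FPKM in round spermatids, and the snRNA Gm24871 at 40.9, 26.9 and 17.9 in pachytene and at 0 in round spermatids. The snRNA Gm25308 and the lincRNA RP23-145J9.11 rose by 5.81 and 5.73 on the log2 scale, folds that rest on pachytene replicate 3 and on pachytene replicate 1, the only library of that stage above 0 for each. Gm13821 fell from 29.4 ± 5.09 to 1.70 ± 0.621 FPKM. The histone gene Hist1h2br was at 10.6, 39.5 and 0.303 FPKM in the 3 round spermatid libraries, and its log2 fold change of 5.15 is 3.73 without replicate 2 and 7.04 without replicate 3. The snoRNA Gm22362 was listed at 0 in pachytene and at 34.6, 16.5 and 0 FPKM in round spermatids, and the snoRNAs Gm25588 and Gm24900 fell (log2 fold changes -5.35 and -5.32), with only round spermatid replicate 1 above 0 in the later stage. The calls of Gm22362, Gm25588 and Gm24900 ended in alternatives with fewer libraries (adjusted p up to 0.0985, 0.0890 and 0.0748). The snRNA Gm23027 fell (log2 fold change -4.73), with only round spermatid replicate 3 above 0 in that stage.

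Of 32 acrosome and sperm-egg binding genes 20 rose and none fell, with a median log2 fold change of 3.56, the same adjusted over the list alone (adjusted p = 1.17e-06; adjusted p = 0.0795 with an estimated correlation). Spaca7 rose by 3.74, the sperm hyaluronidase Spam1 by 3.70 and the acrosomal protein Acrv1 by 3.68 on the log2 scale. Of 36 flagellum genes 27 rose and 2, the dynein heavy chains Dnah1 and Dnah8, fell, also over the list alone (adjusted p = 1.49e-06; adjusted p = 0.0795 with an estimated correlation). The sperm calcium channel genes Catsper3, Catsper4 and Catsper1 rose by 3.72, 3.71 and 3.66, and the kinase gene Tssk4 by 3.65. Of 20 genes of spermatid chromatin and transcription 13 rose and 3 fell, also over the list alone (adjusted p = 0.00919; adjusted p = 0.351 with an estimated correlation). The CREM partner Fhl5 rose from 21.4 ± 1.19 to 263 ± 12.5 FPKM, the spermatid linker histone gene Hils1 from 62.4 ± 5.93 to 756 ± 11.3, and H1fnt by 3.49 on the log2 scale, and Gmcl1, Kat5 and Rnf8 fell. Of 26 glycolysis genes 9 rose and 4 fell, also over the list alone, and the list did not pass (adjusted p = 0.530), with the testis aldolase copies Aldoart2 and Aldoart1 up by 3.64 and 3.62, Gapdhs up by 3.54 and Gpi1 up by 2.21 on the log2 scale.

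Of 23 genes on the piRNA list 9 fell and 1, Gtsf1, rose, the same adjusted over the list alone (adjusted p = 0.00113; adjusted p = 0.743 with an estimated correlation), with Tdrd5 at 106 ± 1.49 FPKM in pachytene and 16.2 ± 0.170 in round spermatids, and Tdrd1 and Pld6 down (log2 fold changes -2.53 and -2.51). Of 26 genes of pachytene and the meiotic divisions 5 rose and 6 fell, also over the list alone, and the list did not pass (adjusted p = 0.530). The phosphatase gene Cdc25c rose by 2.59 and Ccnb3 by 2.28, and Cks2 fell from 484 ± 18.9 to 81.9 ± 4.60 FPKM. Of 34 synaptonemal complex and recombination genes 8 rose and 9 fell, also over the list alone (adjusted p = 0.646, median -0.05, mean 0.19, test direction down), with the meiotic cohesin genes Rec8 and Rad21l up by 3.50 and 2.50 and Tex15 and Tex11 up by 3.21 and 2.74. Of 16 genes of differentiating spermatogonia 11 rose and none fell, also over the list alone (adjusted p = 0.00506; adjusted p = 0.351 with an estimated correlation). Cyclin D3, Ccnd3, rose from 6.85 ± 0.575 to 75.1 ± 5.01 FPKM, X-linked Rhox13 by 3.04, Crabp1 by 2.10 and Prdm9 by 2.06 on the log2 scale. Of 25 genes of undifferentiated spermatogonia 5 rose and 6 fell, also over the list alone (adjusted p = 0.890, median 0.24), with Id4 and Egr4 down (log2 fold changes -2.62 and -2.47) and Gfra1 and Lhx1 up by 2.25 and 1.93, and the call of Lhx1 ended with a pseudocount of 1 FPKM. Of 33 DNA replication genes 7 rose and 3 fell, also over the list alone (adjusted p = 0.916, median 0.08), with Fen1, Mcm2, Rrm2 and Mcm4 up by 2.40, 1.95, 1.74 and 1.73. With equal library medians the medians of both lists turned negative, to -0.12 and -0.27. Of 57 ribosomal protein genes 1, Rpl10, rose and none fell, also over the list alone (adjusted p = 0.0710), and Rps28 and Rpl32 had log2 fold changes of 0.05 and -0.10. That list passed as lower with equal medians (adjusted p = 0.000488), with no filter (0.0170), without pachytene replicate 1 (0.0402) or 3 (0.0471) and with replicates 1 and 2 only (0.0397).

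Sertoli markers fell further, and Leydig markers, which had gone both ways into pachytene, fell, beside the piRNA genes. Of 23 Sertoli markers 17 fell and 1, Krt18, rose, the same adjusted over the list alone (adjusted p = 3.57e-06; adjusted p = 0.132 with an estimated correlation), with Clu at 182 ± 4.59 FPKM in pachytene and 41.4 ± 1.52 in round spermatids, and Inhbb, Cldn11 and Wt1 down (log2 fold changes -2.19, -2.04 and -1.81). Of 11 Leydig markers 8 fell and none rose, also over the list alone (adjusted p = 0.00113; adjusted p = 0.0795 with an estimated correlation), with Insl3 at 14.2 ± 4.29 FPKM in round spermatids and Cyp11a1, Hsd3b1 and Hsd17b3 down (log2 fold changes -1.83, -1.79 and -1.74). The call of Hsd17b3 ended with a pseudocount of 1 FPKM. Fibroblast and interstitial markers went the other way, beside the acrosome and flagellum genes, with 8 of 10 up, also over the list alone (adjusted p = 0.0214; adjusted p = 0.743 with an estimated correlation), and the list lost its call with a pseudocount of 1 FPKM (adjusted p = 0.121). Dcn, a matrix proteoglycan, rose from 0.691 ± 0.162 to 17.0 ± 1.05 FPKM, Igf1 by 2.98 and Col1a2 by 2.67 on the log2 scale, and Lum, up by 3.08, lost its call with that pseudocount.

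Of 13 macrophage markers 11 rose over all genes and 12 adjusted over the list alone, and 1, Mrc1, fell (adjusted p = 0.132). The complement gene C1qa rose from 0.442 ± 0.268 to 5.69 ± 1.08 FPKM and the lysozyme gene Lyz2 from 1.12 ± 0.0740 to 13.0 ± 0.995, with C1qc and Tyrobp up by 3.73 and 3.56 on the log2 scale. The macrophage list passed with equal library medians (adjusted p = 0.0263), without spermatogonia replicate 3 (adjusted p = 0.0069) and with only the 6 libraries compared (adjusted p = 0.00663). Of 10 endothelial markers 3 rose, also over the list alone (adjusted p = 0.677, median 0.30, and -0.05 with equal medians): Kdr by 1.45, Egfl7 by 1.33 and Tek by 1.21. The calls of Kdr and Tek ended with a pseudocount of 1 FPKM, and those of Egfl7 and Tek with equal medians. Of 9 myoid markers 1, Actg2, rose, from 16.8 ± 0.300 to 193 ± 3.53 FPKM, and Acta2 stood at 10.6 ± 0.478 in round spermatids, also over the list alone (adjusted p = 0.250). Of 5 erythroid markers 1, Alas2, fell, also over the list alone (adjusted p = 0.530), and Hbb-bs and Hba-a1 were not called, at 0.401 ± 0.0691 and 0.284 ± 0.362 FPKM in round spermatids.

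In all, 7333 of 17987 features changed between pachytene and round spermatids, 4915 up and 2418 down, and 8 of the 19 lists passed, none with an estimated correlation. The balance depends on the scaling: 67.0% of the changed features rose with the deposited values, and 49.2% (3986 up and 4115 down) with equal library medians, which moved the median change from 0.13 to -0.23 on the log2 scale. The authors' deposited table lists 5076 features higher and 4284 lower in round spermatids with no fold threshold, 3650 and 2013 of them at 2-fold.

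**Figure D2:**
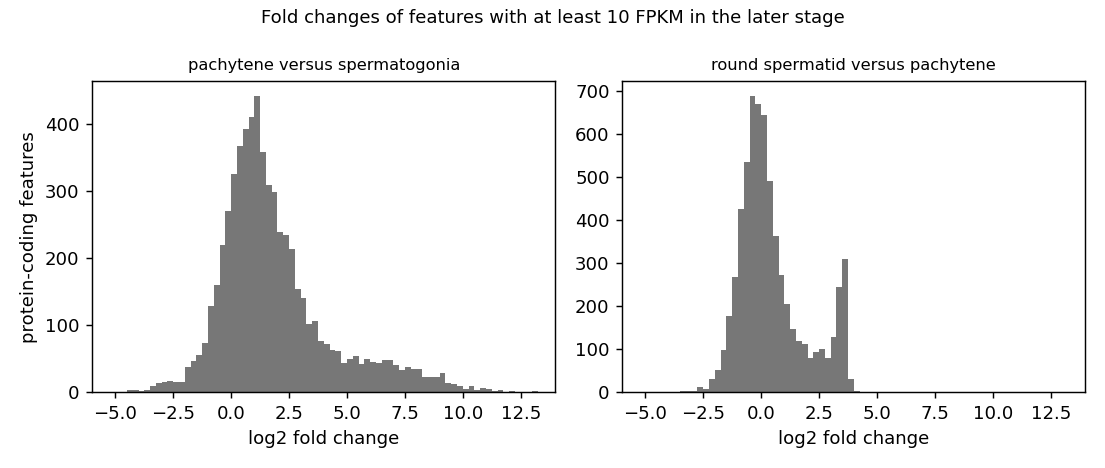
Log2 fold changes of the coding features with at least 10 FPKM in the later stage of each transition, on an axis of log2(FPKM + 0.1). The 99th percentile is 3.70 from pachytene to round spermatids, with a highest value of 5.15, and 9.59 from spermatogonia to pachytene, with a highest value of 13.41.

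Long non-coding RNAs were measured on their own scale in the lncRNA table. The lincRNA 1700042G15Rik, on chromosome 4 from 57360868 to 57364292, was listed at 0 in the spermatogonia libraries and at 4849, 4311 and 7351 FPKM in pachytene, and 1700026J12Rik, on chromosome 16, at 0 and at 3906, 4357 and 4898. RP24-176G22.2, on chromosome 17 from 49112263 to 49113535, rose from 1.06 ± 0.940 to 34432 ± 8996 FPKM (log2 fold change 15.65, SE 0.991, adjusted p = 2.61e-06), with 14.29 without spermatogonia replicate 1, and by 13.14 in the mRNA table. H19, an imprinted maternal transcript, fell from 1914 ± 695 to 14.2 ± 2.62 FPKM (log2 fold change -7.01, SE 0.295, adjusted p = 2.03e-07). The antisense transcript 1700010K23Rik was listed at 0 in spermatogonia and at 3228, 3363 and 3380 FPKM in pachytene, and shares 256 bp of exon with a coding gene on the other strand, so its value is uncertain. The lincRNAs RP23-258N15.1 and RP23-408K8.2 were listed at 0 in spermatogonia, at 2330, 2207 and 2344 FPKM and at 1897, 2184 and 1999 in pachytene.

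The largest falls were mostly to values listed at 0 in pachytene. In the spermatogonia libraries RP23-189P1.2 was listed at 47.7, 64.4 and 237 FPKM, RP23-457H19.1 at 100, 43.6 and 88.5, Gm15334 at 84.1, 26.9 and 33.7, and X-linked 3010001F23Rik at 18.3, 45.3 and 25.7. RP23-189P1.2, RP23-457H19.1 and 3010001F23Rik share exon sequence with a coding gene on the other strand (134, 347 and 122 bp). Fcor, coding in M21, was listed at 99.6, 66.7 and 38.2 FPKM, and RP23-28L24.8 fell (log2 fold change -8.52). The latter has 1 pachytene library above 0, replicate 3, on which the fold rests, and without replicate 1 or 2 it is -7.26. In the mRNA table RP23-189P1.2, RP23-457H19.1, Fcor, Gm15334 and RP23-28L24.8 fell too (log2 fold changes -4.16, -4.07, -3.98, -3.81 and -4.24).

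Of 32 tested known lncRNAs 19 fell, 4 rose and 9 were not called, the same adjusted over the list alone (adjusted p = 0.00143; adjusted p = 0.300 with an estimated correlation). Sertoli, fibroblast, endothelial and myoid markers fell in the same comparison, 56 of 70 markers of 6 cell types, so these falls need not be of germ cells. The scale of the table also shifted. Over 254 features, its median log2 ratio to the mRNA table was 5.46 ± 0.16 in spermatogonia and 4.90 ± 0.08 in pachytene. Part of these falls may therefore come from the separate scaling. Imprinted transcripts were not tested as a group and did not all move alike. Meg3 fell from 103 ± 3.68 to 4.89 ± 3.59 FPKM, Rian from 1046 ± 106 to 47.1 ± 18.8, and Airn and Kcnq1ot1 likewise (log2 fold changes -4.79 and -2.13), while Mirg, of the Meg3 region, was not called (log2 fold change -0.88, adjusted p = 0.0585) and Nespas, which shares 988 bp with a coding gene on the other strand, rose by 1.70. X-linked Xist, the RNA of X inactivation in females, which shares 431 bp of exon with a coding gene on the other strand, fell from 8.76 ± 3.25 to 0.216 ± 0.265 FPKM, Ftx from 71.6 ± 11.1 to 7.87 ± 2.96, Firre from 323 ± 88.5 to 41.1 ± 5.72, and Jpx also fell (log2 fold change -4.10). The fold of Jpx is -2.30 without pachytene replicate 2 and -5.24 without replicate 3, and its call was lost in 6 alternatives with fewer libraries (adjusted p up to 0.0863).

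Among other known lncRNAs, the nuclear RNA Malat1 fell from 34711 ± 16421 to 5846 ± 3026 FPKM, and the snoRNA hosts Snhg1 and Snhg4 fell (log2 fold changes -3.04 and -3.49). Gas5, Snhg6, Snhg12 and Dancr fell (log2 fold changes -1.07, -1.41, -1.14 and -1.20) in the lncRNA table only: in the mRNA table they were not called, with log2 fold changes of -0.61, -0.80, -0.03 and 0.08. The lower ratio between the tables in pachytene goes the same way as this gap, and was not tested as its cause. Dnm3os, Fendrr and Tunar, the last coding in M21, fell (log2 fold changes -2.28, -3.01 and -3.93). The fold of Tunar is -2.83 without pachytene replicate 3 and -4.98 without replicate 1. The call of Fendrr ended without spermatogonia replicate 2 (log2 fold change -2.65, adjusted p = 0.0711) or without pachytene replicate 2 (log2 fold change -2.25, adjusted p = 0.0524). The call of Gas5 ended without spermatogonia replicate 1 (log2 fold change -0.86) or 2 (-0.94). Miat rose from 0.433 ± 0.279 to 26.8 ± 13.9 FPKM, Hotair by 5.99 on the log2 scale (a fold that rests on spermatogonia replicate 1, the only library of that stage above 0), and Pvt1 from 28.4 ± 3.61 to 188 ± 26.4 FPKM.

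In all, 2267 of 4009 features of the lncRNA table changed, 1266 up and 1001 down. The share of rises depends on the scaling and on which features are tested. It was 55.8% with the deposited values and 49.0% (1156 up and 1201 down) with equal library medians. Division by the ratio to the mRNA table leaves only 2319 features tested, with 1267 up and 371 down (77.4%), so scale and features change together there. Over the same 1623 features, those also tested in the mRNA table, the share was 67.9% before the division and 73.9% after it, and by mRNA-table values 842 rose and 298 fell. The authors' deposited table lists 927 higher and 703 lower with no fold threshold, 830 and 591 of them at 2-fold. Strand use in counting is not known, so reads of overlapping genes may be shared, and of 2408 features that share no exon with a coding gene 837 rose and 538 fell.

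From pachytene to round spermatids, several lincRNAs appeared. RP23-331P8.5, on chromosome 9 from 92301963 to 92305144, was listed at 0 in all spermatogonia and pachytene libraries and at 140, 120 and 306 FPKM in round spermatids, and RP23-52N2.4 and RP24-348G21.1 at 0 and at 28.0, 56.5 and 57.6 and at 16.2, 13.5 and 53.6. The antisense transcript Gm14547 was listed at 0 in pachytene and at 21.7, 27.3 and 35.5 FPKM in round spermatids, RP23-145J9.11 at 102, 0 and 0 and then 496, 410 and 529, and antisense Gm13274, which shares 635 bp with a coding gene on the other strand, at 0, 0 and 34.6 and then 140, 157 and 238. The folds of RP23-145J9.11 and Gm13274 (log2 fold changes 8.88 and 7.95) rest on the 1 pachytene library above 0, and are 7.22 and 6.54 when 1 of the other 2 is left out. The calls of RP23-145J9.11 and Gm13274 ended in alternatives with fewer libraries (adjusted p up to 0.184 and 0.0586). Among falls, Gm26893 was listed at 10.7, 7.48 and 10.2 FPKM in pachytene and RP24-136L4.1 at 5.003, 6.03 and 11.2, both at 0 in round spermatids. A430104N18Rik, Gm11795, Gm27032 and Gm20554 fell (log2 fold changes -6.95, -6.66, -6.46 and -5.74). The folds of A430104N18Rik, Gm11795 and Gm20554 rest on round spermatid replicate 2, the only library of that stage above 0. Single libraries also move the folds, to -5.94 and -5.65 for A430104N18Rik and Gm11795 without replicate 1 or 3, and to -5.02 for Gm27032 without replicate 3. The call of Gm20554 ended without any 1 pachytene library, without round spermatid replicate 1 or 3 (adjusted p up to 0.0983) and with the replicate number as a block (0.0602). With replicates 1 and 2 only the calls of A430104N18Rik, Gm11795 and Gm20554 ended (adjusted p = 0.0976, 0.108 and 0.184).

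Of 32 known lncRNAs 6 rose, 6 fell and 20 were not called, also adjusted over the list alone (adjusted p = 0.175, median -0.12, mean 0.13, test direction down). X-linked Xist rose from 0.216 ± 0.265 to 2.80 ± 1.62 FPKM and Ftx from 7.87 ± 2.96 to 43.6 ± 4.87, and Mirg, of the imprinted Meg3 region, from 18.2 ± 5.92 to 76.2 ± 16.7. Rian, H19 and Pvt1 rose by 1.49, 1.24 and 1.35 on the log2 scale, below the fold threshold with equal medians (0.84, 0.59 and 0.71). The snoRNA hosts Snhg3, Snhg12 and Snhg5 fell (log2 fold changes -1.80, -1.49 and -1.09), the microRNA host Mir17hg from 310 ± 58.8 to 118 ± 34.0 FPKM, and Dnm3os and Nespas fell (log2 fold changes -1.95 and -1.69). Snhg3 shares 135 bp of exon with a coding gene on the same strand, so its value is uncertain. Snhg5 lost its call without pachytene replicate 3 or round spermatid replicate 2 (log2 fold changes -0.93 and -0.96) and in the mRNA table (-0.94). Dnm3os lost it with replicates 1 and 2 only (adjusted p = 0.0587).

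In all, 1263 of 4009 features changed, 902 up and 361 down. The share of rises was 71.4% with the deposited values and 48.0% (706 up and 764 down) with equal medians. After division by the ratio to the mRNA table it was 76.0% (897 up and 284 down), but of 2319 features rather than 4009, and over the same 1623 features it was 69.2% before and 75.9% after. Equal medians moved the median change of all features from 0.38 to -0.26 here and from -0.02 to -0.39 in the earlier transition. The authors' deposited table lists 929 higher and 605 lower with no fold threshold, 799 and 375 of them at 2-fold.

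Transcripts of the X chromosome, which is silenced in pachytene, were compared with those of autosomes. In the mRNA table, 518 of 795 X-linked features fell and 170 rose into pachytene (65.2% down, against 29.5% of autosomal features), with Rps4x, Rpl10 and Tex11 among the former. The X minus autosome difference of median log2 fold changes was -2.62 (camera p = 6.69e-10; p = 0.00887 with an estimated correlation). Per library the X median lay below the autosomal one by a log2 difference of -0.58 ± 0.11 in spermatogonia, -2.53 ± 0.05 in pachytene and -1.30 ± 0.05 in round spermatids. In round spermatids 497 of the 795 rose and 46 fell (62.5% up, against 25.3%), with Rhox13 and Tex11 among the rises, a difference of 1.48 (camera p = 1.16e-11; p = 0.00577 with an estimated correlation). X-linked lncRNAs moved likewise: 62 of 117 fell into pachytene (difference -2.74, camera p = 3.95e-05; p = 0.00337 with an estimated correlation), with Firre and Ftx among them. In round spermatids 40 of the 117 rose (1.61, camera p = 0.007; p = 0.0218 with an estimated correlation), and among lncRNAs that share no exon with a coding gene the later difference was 1.30 (p = 0.0801). The exact two-sided permutation test gave p = 0.1 for each of the 4 differences, the smallest that 3 libraries against 3 allow.

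**Figure D3:**
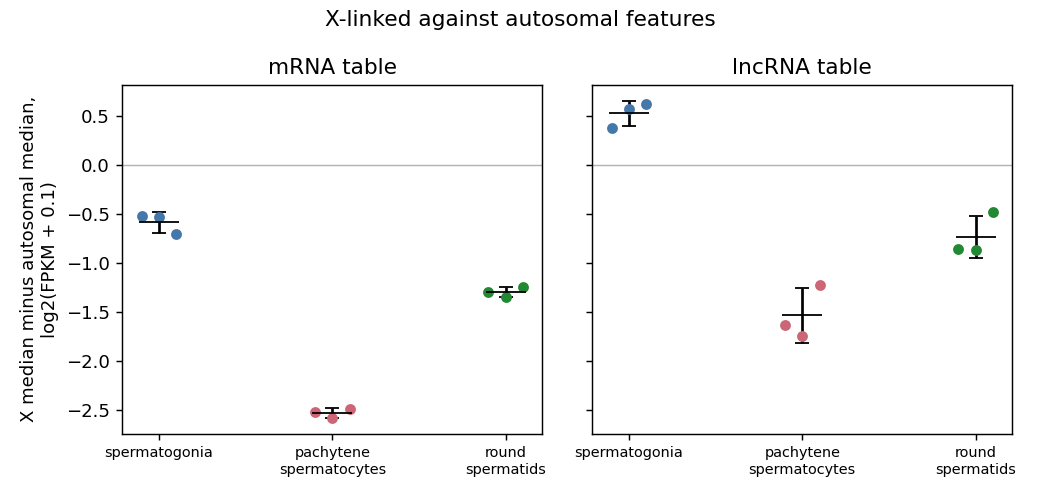
Median log2(FPKM + 0.1) of X-linked minus that of autosomal features in each library, for both tables, with a line at the mean of 3 libraries. The difference is lowest in pachytene, at -2.53 ± 0.05 in the mRNA table and -1.54 ± 0.28 in the lncRNA table.

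Features highest in a single stage were counted last. In the mRNA table, 4376 features (24.3%) were highest in spermatogonia, as Zbtb16 and Mcm2 were, 1295 (7.20%) in pachytene, as Hist1h1t and Piwil1 were, and 3200 (17.8%) in round spermatids, as Tnp1 and Lyzl6 were. In the lncRNA table the counts were 717 (17.9%), as H19 and Rian, 198 (4.94%), and 703 (17.5%). The share in pachytene depends on the scaling, with 1993 mRNA-table and 307 lncRNA-table features under equal medians. The difference between the tables was not tested.

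**Figure D4:**
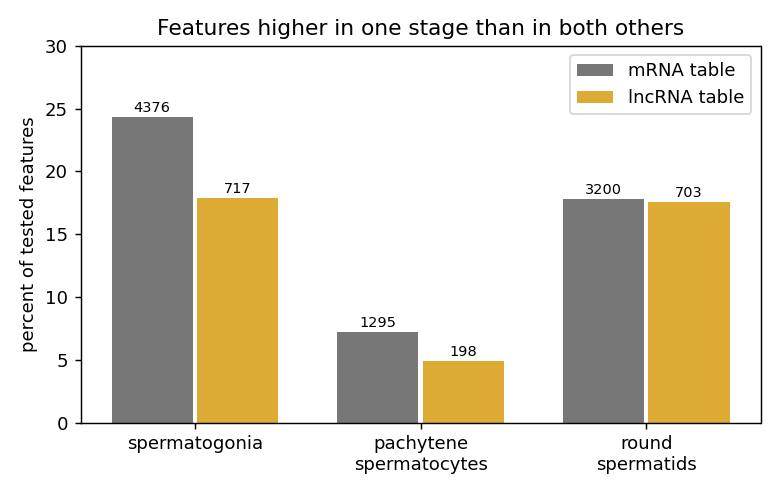
Percent of tested features that limma calls higher in a stage than in both others, for both tables. Pachytene has the smallest share in each, 7.20% and 4.94%.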

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

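Each count was recomputed under the alternatives. A count was labelled the same if it stayed within 1.5-fold of its main value. An X minus autosome difference was labelled the same if its sign and its camera call at p under 0.05 held. By these rules 270 values stayed the same, 13 moved and 1 weakened, so values labelled the same can still differ. With no fold threshold 13453 mRNA-table features changed in round spermatids and 3725 were highest in pachytene, and 1993 were with equal library medians. In the lncRNA table, values of the same genes in the mRNA table gave 1140 and 840 changed features and 216 highest in spermatogonia. Features with no shared exon gave 1375 and 808 changed, 386 highest in spermatogonia and 117 in pachytene, and equal medians gave 307 in pachytene. The later X minus autosome difference of lncRNAs weakened to 1.30 with no shared exon. With an estimated correlation 2 and 0 lists passed. Fewer features were tested with mRNA-table values and with no shared exon, and the cause of the other shifts was not tested. Those using the mRNA table, shared exons, replicates 1 and 2 only, coding features only or a removed spermatid share were chosen after the data were seen.

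Single genes and lists were labelled by direction and call, not by the size of the change. By that rule 4060 values stayed the same, 96 weakened, 13 strengthened and 4 reversed. Des, at -3.09 and at -1.32 without spermatogonia replicate 3, is among the values labelled the same. The reversals were the list medians in round spermatids under equal medians of undifferentiated spermatogonia (-0.123), DNA replication (-0.274) and endothelial markers (-0.0543), none of them passing, and Dancr into pachytene with mRNA-table values (0.0772), and the cause was not tested.

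Leaving each library out in turn gave 12075 to 12150 and 7236 to 7394 changed mRNA-table features, 2069 to 2302 and 1066 to 1337 in the lncRNA table, and 14 to 15 and 8 to 9 lists. The X minus autosome differences ran from -2.63 to -2.57 and 1.48 to 1.51 in the mRNA table, and from -2.89 to -2.31 and 1.26 to 1.74 in the lncRNA table. Features highest in spermatogonia, pachytene and round spermatids numbered 4326 to 4392, 1271 to 1313 and 3162 to 3275 in the mRNA table, and 551 to 690, 162 to 213 and 577 to 744 in the lncRNA table.

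Replicate numbers do not pair the samples: deviations from the stage mean of libraries with the same number correlated at -0.106 to 0.0388 in the mRNA table and -0.0379 to 0.0986 in the lncRNA table. With the number as a block 12162 and 7338 mRNA-table and 2287 and 1296 lncRNA-table features changed, and of the named genes Gm20554 lost its call.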

Other observations

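Most features of chromosome Y rose into pachytene, where most of the X fell, and in round spermatids most features of both rose. The X was a planned group, and its test is given above. The Y, snoRNA and scaRNA groups were picked after their values were seen, and no test was run of them. Of 110 features of the Y in the mRNA table, 69 rose and 12 fell into pachytene, with a median log2 fold change of 1.42, and 104 rose and 1 fell in round spermatids, with a median of 3.15. That median lies near 3.16, the 90th percentile for coding features with at least 10 FPKM in round spermatids, and below their 99th, 3.70. Spermatid RNA in the pachytene libraries could contribute to rises of the Y into pachytene, which was not tested. Ddx3y, a helicase gene of the Y, was among the few that fell, from 22.8 ± 2.47 to 1.95 ± 0.108 FPKM (n = 3 each), as did Kdm5d, Uty and Usp9y (log2 fold changes -3.82, -3.58 and -3.11). Zfy1 and Zfy2, zinc finger genes of the Y, fell (log2 fold changes -1.18 and -1.43) and then rose by 3.16 and 3.02. Of 139 tested snoRNAs 96 fell and 3 rose into pachytene, and of 19 scaRNAs 15 fell and 1 rose, where 5570 of all 17987 features fell. The 10 highest features held 34.4%, 30.6% and 30.7% of the summed FPKM in the spermatogonia libraries, and 9.67%, 10.6% and 9.49% in pachytene. The libraries of these stages thus differ in make-up, and its bearing on the snoRNAs and scaRNAs was not tested.

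Genes on the X with an autosomal copy moved apart from that copy. This test was chosen after the values were seen, and all 15 pairs looked at are kept. The X-linked gene fell into pachytene in all 15, and in 13 the copy rose, where 36.6% of all features rose. Pgk1 fell and Pgk2 rose (log2 fold changes -3.08 and 10.62), as did Pdha1 and Pdha2 (-3.89 and 5.94), Rpl10 and Rpl10l (-4.02 and 4.09) and Cetn2 and Cetn1 (-3.06 and 10.74). Pgk1 and Pdha1 varied widely between the spermatogonia libraries, at 23.9 ± 13.2 and 24.9 ± 23.7 FPKM. The exceptions were Utp14b and Rps4l, not called (0.36 and 0.78). The pairs were picked because such copies are known to be expressed in meiosis, so this count cannot be set against chance.

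Long non-coding RNAs near a coding gene changed with it. The prediction was written before its values were computed. Across 1184 pairs within 5 kb that share no exon, log2 fold changes correlated at r = 0.378 in pachytene against spermatogonia and 0.342 in round spermatids against pachytene (highest of 10000 shuffles 0.103 and 0.131, permutation p = 0.0001 for each, the smallest possible). The shuffles were over pairs of features, not over libraries, so these p-values do not measure the spread between samples. Features are not independent replicates, which the shuffles do not allow for. Without the X and Y the correlations over 1158 pairs were 0.367 and 0.346. Pairs on opposite strands gave 0.374 and 0.351 (932 pairs) and those on the same strand 0.392 and 0.306 (252 pairs). Unannotated extensions of the coding transcript could give such a correlation on the same strand. If counting used the strand, they would not give the 0.374 and 0.351 of the 932 pairs on opposite strands. Whether it did is not known, so reads of the coding gene could be counted for a lncRNA on either strand. These correlations therefore do not separate such reads from shared regulation.

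Few rises from pachytene to round spermatids exceed a log2 fold change of 4, and all tests of this were chosen after the result was seen. Of 6402 coding features with at least 10 FPKM in round spermatids, 0.0781% do so, and Akap4, Tnp1 and Catsper3 lie at 3.52, 3.51 and 3.72. Among the 2488 coding features with at least 50 FPKM in round spermatids, the 99th percentile was 3.70 with the pseudocount and 3.72 without it. The pseudocount is therefore not the source of the limit for those features, and features under 50 FPKM were not checked without it. A low and even share of spermatid RNA in the pachytene libraries could give the limit. Low transcription of spermatid genes in pachytene cells stays open: the interquartile range over all 808 coding features under 0.5 FPKM in spermatogonia, 3.05, takes in genes already on in pachytene (lower quartile 0.51), and that over the 555 called rises, 0.375, is of genes picked for the pattern. In the lncRNA table, 62 of 1346 features with at least 50 FPKM exceed 4. Its round spermatid values are by median 24.8 to 26.8 times those of the mRNA table, so 50 FPKM admits lower features there. Of the 62, 40 are listed at 0 in at least 1 pachytene library, so those 40 decide nothing. The rest are above 0 in every pachytene library and still exceed 4. Because the threshold is unlike that of the coding features, they do not decide on the limit either.

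Markers of somatic testis cells were higher in spermatogonia, and all tests of this were chosen after the result was seen. Of 70 tested markers of 6 lists, Leydig set apart, 56 (80%) fell into pachytene, Col1a2 and Amh among them. Sertoli, stromal and blood cells in the spermatogonia libraries could give this. For macrophages the comparison with pachytene is not the whole of it. The mean log2 level of that list was -0.12, -0.29 and 2.15 in the spermatogonia libraries and 1.34, 1.34 and 1.42 in round spermatids. Only spermatogonia replicate 3 was above round spermatids. A larger share of every cell type alike would lower the Leydig markers too, but 4 of them rose, Insl3 among them, and 4 fell. Markers that disagree do not measure a share of Leydig cells, so they do not decide this. Expression of the markers by spermatogonia stays open, and the erythroid list does not decide it. The mean of that list spans 2.03 on the log2 scale over the spermatogonia libraries, and 0.207 without replicate 3. The outcome of that test thus rests on a single library.

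The share of rises into pachytene was lower in the lncRNA table, 55.8% of its changed features, than in the mRNA table among the 1623 features tested in both, 73.9%, and all tests of this were chosen after the result was seen. The 18.0 points between them set unlike features side by side: over the same 1623 features the lncRNA table has 67.9%, which closes 66.7% of the gap and leaves 6.0 points. Features that pass the filter only in the lncRNA table could thus account for most of it. Among features that share no exon with a coding gene the gap is 2.66 points (72.9% and 75.6%), so reads shared with coding exons could account for part of the rest. Separate scaling stays open too, since division by the ratio between the tables gives 73.9% over the features it was taken from and so sets the tables alike.

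Other groupings of the libraries were tried for each count, a test chosen after the results were seen. With 6 libraries there are 10 splits, and 10 splits cannot reach 0.05. The real split gave 12101 changed mRNA-table features and the highest other 1, and for round spermatids 7351 and 4. In the lncRNA table the values were 2239 and 0, and 1283 and 20, so that 1 of 10 splits reached the real value each time. For gene lists the real split gave 14 and the highest other 15, with 5 of 10 splits at least as large, and 9 and 9 in the later transition, with 3 of 10. For features highest in a single stage, 1 of 100 splits reached the real value in each table, 8871 against 4547 and 1618 against 612.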
